A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

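RNA bound by the m6A reader Pho92 was profiled by CRAC (UV crosslinking and purification of a tagged protein under denaturing conditions, with sequencing of the RNA that stays attached) in diploid SK1 budding yeast. The cells carried IME1, the master regulator of meiotic entry, under a copper-inducible promoter. Per the labels' protocols, they were collected 5 h after transfer to sporulation medium, 3 h after induction with 50 μM copper sulfate, and irradiated at 254 nm for 80 s, except in the group without UV. The 8 libraries fall into 4 groups of 2, named by the labels: Pho92-HTP, Pho92-HTP in an ime4 mutant (IME4 encodes the m6A methyltransferase), Pho92-HTP without UV, and untagged wild type. The series text calls the 2 libraries of a group biological replicates. Crosslinked fission yeast cells carrying Luc7-HTP were added to every sample in equal amount as a spike-in.

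The authors deposited 1 peak list per library and 1 normalization table. The submitters' processing notes name cutadapt, Bowtie2 2.4.1 and the fission yeast build ASM294v2, and reads were 75 nt long per the labels. The peak caller is not given in the sources used here. Peaks are listed per library on SK1 contigs, with strand, and were not pooled over replicates. Whether their coordinates count from 0 or 1 is not stated, and they are printed as in the lists. Each peak carries a score per the file headers (h2w score). From the values, this score equals the squared peak height divided by the peak width, where height is a read density smoothed by a Gaussian with an SD of 15 nt. Among peaks with a width of 32 nt, 63.3% to 92.4% per library had a height within 0.01 of a whole number of reads under this reading. Heights are therefore given as read equivalents, and a log2 difference in score is close to 2 times the log2 difference in height. The formula was worked out from the values, and total reads per library are unknown, so no counting error is attached to any peak.

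The deposited normalized score is the score times 1 factor per library. Per the file headers the factor is a ratio, the spike-in score of Pho92-HTP replicate 1 over that of the library, and the authors count peaks with a normalized score above 0.9. The factors in the sheets were 1 and 5.92 for Pho92-HTP and 1.73 and 1.01 for the ime4 mutant. The deposited control sheets disagree with the deposited table. The no-UV sheets were scaled by 0.428 and 0.746, which the table lists for untagged wild type, and the untagged sheets by 1.13 and 0.771, which it lists for no UV. The table also gives 2138 peaks for no-UV replicate 2, whose sheet holds 2462. The sheets' own factors were used, with the table's factors as an alternative, and the control libraries are named throughout by their labels.

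Peaks of the 4 irradiated Pho92-HTP libraries that touched on the same strand were merged into 105079 regions, with a median length of 33 nt. A region's value in a library is the sum of its normalized scores, and 0 where no peak is listed. A listed 0 is not proof of absence, since a shoulder of a stronger neighbour may carry no peak of its own. Regions above 0.9 in at least 2 of the libraries of a fit were tested. The plan named a count test for counts and limma for any other unit, and since the unit is a score, limma 3.58.1 (R 4.3.3) with a mean-variance trend was applied to log2(normalized score + 2.28e-05), the pseudocount being percentile 5 of all normalized scores. Fold changes are on that scale and depend on the pseudocount for regions listed at 0. Where both libraries of a group are listed at 0, that group adds no spread, so the SE and p there also rest on the listing. Adjusted p is Benjamini-Hochberg, with a threshold of 0.05. Pho92-HTP against the ime4 mutant was fitted on those 4 libraries, and comparisons with controls on all 8. Whole-library totals are given as values only, because the smallest two-sided exact p for 2 against 2 libraries is 0.33. Overlaps of peak lists required 1 bp on the same strand, and chance was taken from 20 shifts of positions along each contig. Wilson intervals of overlaps count peaks as independent and do not measure spread over libraries. Other work used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

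The procedure was tested on simulated data with normal noise and the spread of each real region, averaged over the groups of a fit. All groups thus had the same spread, and no value was set to the level of no listed peak. Real regions can lack a listed peak in both libraries of a group, so the shares below may not hold for the real fits. For Pho92-HTP against the ime4 mutant, with 961 regions, it called 42.9% of simulated log2 changes of -4, 68.1% of those of -8 and 82.4% of those of -12, and 0.263% of unchanged regions. For Pho92-HTP against untagged wild type, with 964 regions, the shares were 43.1%, 78.8%, 85.5% and 0.393%. Most simulated regions were unchanged, 761 of 961 and 764 of 964. In the real data 577 of 961 fell in the mutant and 914 of 964 were higher than untagged. An adjusted p threshold is looser where more regions change, so the share of unchanged regions called may be higher in the real fits. No peak over 10 read equivalents was identical in position and score between any 2 libraries.

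The comparisons with their tests, the groups, a list of alternatives and the rule for named regions were fixed before the data were examined. Tests of explanations are dated where they are given. The rule takes, among regions past the threshold and above the median of the mean score, the 10 most lowered and up to 10 most raised in the ime4 mutant, plus the 10 highest in Pho92-HTP, plus for each control comparison the 5 largest folds and the 5 highest in the control. Alternatives covered scaling (library total, trimmed mean of log ratios), filters, pseudocount, a replicate block, each library left out, merging within 50 nt, the highest peak per region and a threshold of 0.10. Others were added after the data were seen, such as leaving out contig NCSL01000092.1, restricting to regions listed in all 4 libraries, and the table's factors. The peak coordinates are on SK1 contigs, and no annotation or sequence of that assembly was used here. Gene names, position within genes, sequence motifs, RNA classes and the gene lists fixed beforehand were therefore not analysed here.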

Results

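The CRAC data comprised 8 peak lists from meiotic SK1 yeast, with 2 libraries per group. Pho92-HTP libraries held 66344 and 41604 peaks, ime4 mutant libraries 47377 and 60778, libraries labelled no UV 2925 and 2462, and libraries labelled untagged wild type 2659 and 2138. Summits amounted to 2.87e+06 and 1.29e+06 read equivalents in Pho92-HTP and 1.69e+06 and 2.19e+06 in the ime4 mutant. They amounted to 421065 and 334161 read equivalents without UV and 53223 and 35058 in untagged cells. Of the 4 irradiated Pho92-HTP libraries the thinnest was Pho92-HTP replicate 2, whose spike-in factor of 5.92 placed the score of 0.9 at 82.9 read equivalents for a 32-nt peak, against 202 in replicate 1.

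The first comparison asked how much RNA was recovered per group once scaled to the spike-in. Peaks above the authors' normalized score of 0.9 numbered 1081 ± 28.3 in Pho92-HTP (SD, n = 2) and 334.5 ± 2.12 in the ime4 mutant (SD, n = 2). Controls held 54.5 ± 4.95 such peaks without UV (SD, n = 2) and 26.5 ± 9.19 without the tag (SD, n = 2). The number was 3.23 times higher in Pho92-HTP than in the ime4 mutant, and both Pho92-HTP libraries exceeded both ime4 mutant libraries. The summed score did not separate the genotypes, at 1.65e+06 ± 4.60e+05 in Pho92-HTP and 1.60e+06 ± 79709 in the ime4 mutant (SD, n = 2 each). That sum was dominated by a few peaks: the strongest peak alone held 25.6% to 27.6% of it in Pho92-HTP and 25.3% to 35.1% in the ime4 mutant. Scaled summit heights summed to 3.01e+06 ± 2.01e+05 read equivalents in Pho92-HTP, 2.21e+06 ± 21804 in the ime4 mutant, 2.82e+05 ± 9330 without UV and 43635 ± 18186 in untagged cells (SD, n = 2 each).

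Sums over peaks called per library move with the length called. Peaks covered 1713910 ± 554056 nt in Pho92-HTP, 1722380 ± 302048 nt in the ime4 mutant, 86590 ± 10345 nt without UV and 76666 ± 11908 nt in untagged cells (SD, n = 2 each). The mean normalized score per peak was 33.7 ± 19.4 in Pho92-HTP and 29.9 ± 3.76 in the ime4 mutant (SD, n = 2 each), and it was 111 in both libraries without UV and 2.22 and 0.768 in the untagged libraries. Without UV a single peak held 90.6% and 79.7% of the score, so the mean there does not describe a typical peak. Without spike-in scaling, Pho92-HTP replicate 2 held 490 peaks above 0.9 in place of 1101, and the ratio of peak numbers between the genotypes was 2.51. Totals of 2 against 2 libraries cannot reach a two-sided exact p below 0.33.

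**Figure D1:**
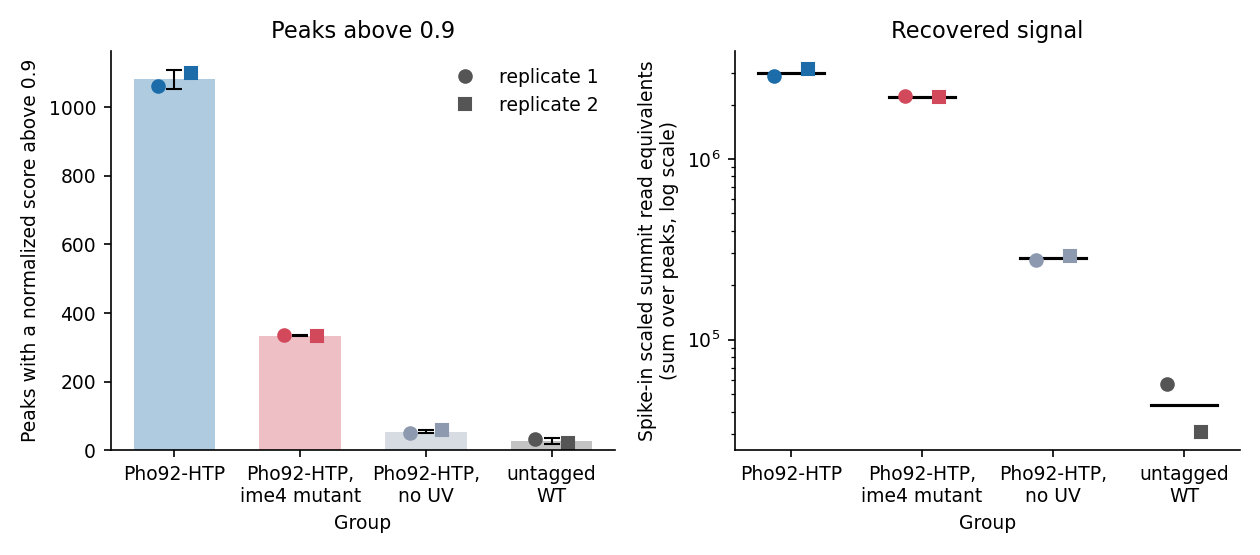
Number of peaks with a normalized score above 0.9 (left; bars are means, error bars SD, n = 2) and sum of spike-in scaled summit heights in read equivalents on a log scale (right; lines are means), with circles for replicate 1 and squares for replicate 2 of each group. Pho92-HTP libraries held 1061 and 1101 peaks above 0.9, and ime4 mutant libraries 336 and 333.

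Replicates shared most of their strong peaks, and a minority of the strong Pho92-HTP peaks was found in the mutant, whose lists above 0.9 were shorter. Of the 1061 peaks above 0.9 in Pho92-HTP replicate 1, 864 overlapped such a peak in replicate 2 (81.4%, 95% Wilson interval 79.0% to 83.7%). Of 336 in ime4 mutant replicate 1, 294 overlapped one in replicate 2 (87.5%, 83.5% to 90.6%). Between the genotypes the share of Pho92-HTP peaks found in an ime4 mutant library was 24.7% to 26.4% over the 4 pairs of libraries. Seen from the mutant most were shared, since 237 of the 293 tested regions above 0.9 in both ime4 mutant libraries were above it in all 4 libraries, and 11 were above it in neither Pho92-HTP library. Shifted positions gave means of 2.23% to 2.46% for these 4 pairs. With weaker peaks included, the overlap of the Pho92-HTP replicates fell to 41.6% over all peaks, with at most 12.5% after shifting. Of all peaks in Pho92-HTP replicate 1, 41.1% and 49.9% overlapped one in ime4 mutant replicates 1 and 2. Of those in Pho92-HTP replicate 2, 47.9% and 55.9% did. Shifting gave at most 14.2% to 18.2% for these pairs. The mutant lists were longer, at 47377 and 60778 peaks against 41604 in Pho92-HTP replicate 2, and the mutant replicates shared 56.9%. The share of 41.6% was counted from Pho92-HTP replicate 1 alone. The contrast thus held for strong peaks. Over all peaks these shares cannot decide it, because list length and direction differ.

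Comparison with the ime4 mutant addressed which Pho92 sites depend on the m6A methyltransferase. Most strong sites were lower without IME4: 577 of 961 tested regions fell, 7 rose and 377 were not called (limma, adjusted p threshold 0.05). The regions that fell lay on 72 contigs and both strands, 290 of them on the plus strand. Their median score was 5.07 and 5.18 in the Pho92-HTP libraries and 0.00680 and 0.00649 in the ime4 mutant libraries. Their median summit went from 491 and 199 read equivalents to 13.1 and 17.8. The median log2 score difference was -10.22 (quartiles -13.69 and -7.42, median SE 1.04), and it was -8.92 over the 443 regions with a peak in all 4 libraries, a 20.6-fold lower height. For 38 of the 577 regions no peak was listed in either ime4 mutant library. Of the 864 regions above 0.9 in both Pho92-HTP libraries, 607 were above it in neither ime4 mutant library. The 377 regions not called had a median difference of 0.27 (quartiles -0.78 and 0.83).

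These counts came from limma on 2 against 2 libraries. With a lone Pho92-HTP library, assumed to vary like the ime4 mutant pair, 73 regions were called without replicate 1 and 70 without replicate 2, while the median difference over all 961 regions stayed at -7.00 and -7.19, against -6.95 with all 4 libraries. Scaling by a trimmed mean of log ratios shifted that median to -6.03 and gave 531 lower and 27 higher regions.

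The 10 most lowered regions scored above the threshold in both Pho92-HTP libraries, and in 8 of them no peak was listed in either ime4 mutant library. On contig NCSL01000013.1 at 275026 to 275058 (plus strand), scores were 218 and 185 in Pho92-HTP and no peak was listed in the ime4 mutant (adjusted p = 0.00154, limma). On NCSL01000087.1 at 2437 to 2470 (plus strand) they were 244 and 83.6, again with none listed in the mutant. The region on NCSL01000014.1 at 43076 to 43119 (minus strand) scored 180 and 246 in Pho92-HTP and 4.97e-05 and 0.00041 in the mutant, where its summits were 1.01 and 4.42 read equivalents (log2 difference -20.18, SE 1.26, adjusted p = 0.00169, limma). Others with no mutant peak lay on NCSL01000031.1 at 94414 to 94446 (69.9 and 48.9 in Pho92-HTP), NCSL01000001.1 at 333220 to 333250 (28.7 and 72.4), NCSL01000008.1 at 59516 to 59549 (5.36 and 39.6) and 280830 to 280862 (19.9 and 8.33). NCSL01000021.1 at 63668 to 63707 scored 105 and 52.1 in Pho92-HTP and had a peak in 1 mutant library. No listed peak did not mean no signal nearby, since all 8 had mutant peaks within 50 nt. Next to NCSL01000005.1 at 130485 to 130515 (86.1 and 48.8 in Pho92-HTP) the mutant libraries held scores of 56.5 and 61.6. The highest scores within 50 nt there were 86.1 and 53.2 in Pho92-HTP, so the strongest local signal was similar in both genotypes. Next to NCSL01000011.1 at 89616 to 89647 (14.8 and 10.8) the mutant libraries held 0.0726 and 2.85. Next to the other 6 the mutant scores were at most 0.504. When regions within 50 nt were merged, the joined regions that held the 10 were all called lower. The differences shrank to between -15.02 and -2.52, among them -8.49 on NCSL01000013.1, -5.73 on NCSL01000005.1 and -2.52 on NCSL01000011.1. Joins chain from peak to peak, so a joined region can reach beyond 50 nt, and its difference may come from other peaks. The calls on NCSL01000014.1 and NCSL01000021.1 were lost with either Pho92-HTP library left out, although the differences stayed at -20.41 and -19.96 and at -19.08 and -20.09. In the other 8 regions both mutant values equal the pseudocount and add no spread. Keeping their calls in those fits therefore does not show them to be sturdier.

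At an adjusted p threshold of 0.05 over 584 calls, the 7 raised regions may include false calls. Of the 7 raised regions, 5 met the rule for naming, and 3 of these had peaks in all 4 libraries. NCSL01000058.1 at 443 to 506 scored 0.362 and 1.96 in Pho92-HTP and 9.38 and 11.9 in the mutant (log2 difference 3.65, SE 1.03, adjusted p = 0.0431, limma). NCSL01000060.1 at 489 to 543 went from 0.935 and 0.733 to 7.23 and 7.99 (3.20, SE 0.55, adjusted p = 0.0108, limma), and NCSL01000008.1 at 273726 to 273771 from 1.47 and 2.13 to 14.1 and 7.46 (2.53, SE 0.63, adjusted p = 0.0296, limma). These 3 calls were lost with either Pho92-HTP library left out, those on NCSL01000058.1 and NCSL01000008.1 also with either ime4 mutant library left out, and those on NCSL01000060.1 and NCSL01000008.1 also without the filter. The call on NCSL01000008.1 was also lost in the fit on all 8 libraries and with a replicate block (adjusted p = 0.0865, limma). The remaining pair had no listed peak in Pho92-HTP but a strong peak within 50 nt there: NCSL01000092.1 at 1455 to 1472, with neighbouring scores of 13327 and 3825, and NCSL01000052.1 at 41444 to 41475, with 12.2 and 4.46. Neither was called when regions within 50 nt were merged, at log2 differences of -0.04 and 1.24. The call on NCSL01000052.1 was also lost with either Pho92-HTP library left out (adjusted p = 0.0618 and 0.0589, limma).

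The strongest sites of all were mostly not called. Among the 10 regions with the highest mean score in Pho92-HTP, 8 lay on contig NCSL01000092.1 and 1 on NCSL01000010.1, and none of these 9 passed the test in either direction, with log2 differences from -0.90 to 0.63. The exception was NCSL01000027.1 at 112222 to 112282 (minus strand), with scores of 47403 and 16797 in Pho92-HTP against 48.1 and 56.0 in the mutant, a fall of -9.09 on the log2 scale (SE 0.73, adjusted p = 0.00262, limma). Contig NCSL01000092.1 held 50 tested regions between 1283 and 5504, all on the plus strand. By limma 0 of the 50 were called lower, also at an unadjusted p under 0.05, 1 was called higher, and the median difference was 0.22. For 39 of the 50 a peak was listed in both untagged libraries. With trimmed-mean scaling 5 of the 9 uncalled strongest regions changed sign, none of them called.

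**Figure D2:**
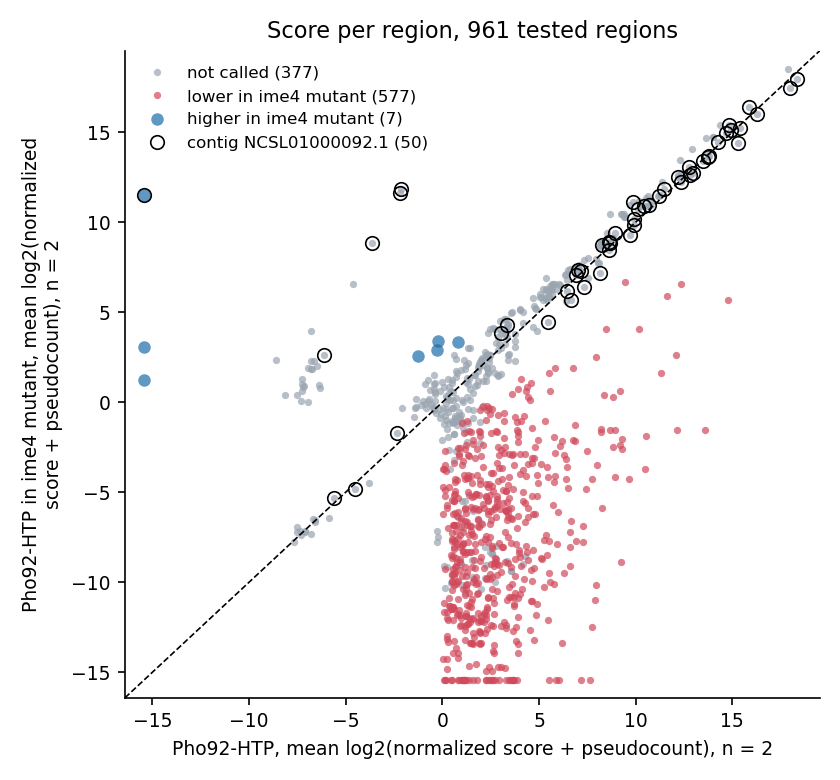
Mean log2(normalized score + pseudocount) of each of 961 tested regions in Pho92-HTP (x axis) and in the ime4 mutant (y axis), n = 2 libraries each, coloured by the limma call, with open circles for regions of contig NCSL01000092.1 and a dashed line of equality. The 577 lowered regions lie below the line, down to the level of no listed peak, and the 50 regions of contig NCSL01000092.1 hold 0 of them.

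**Figure D3:**
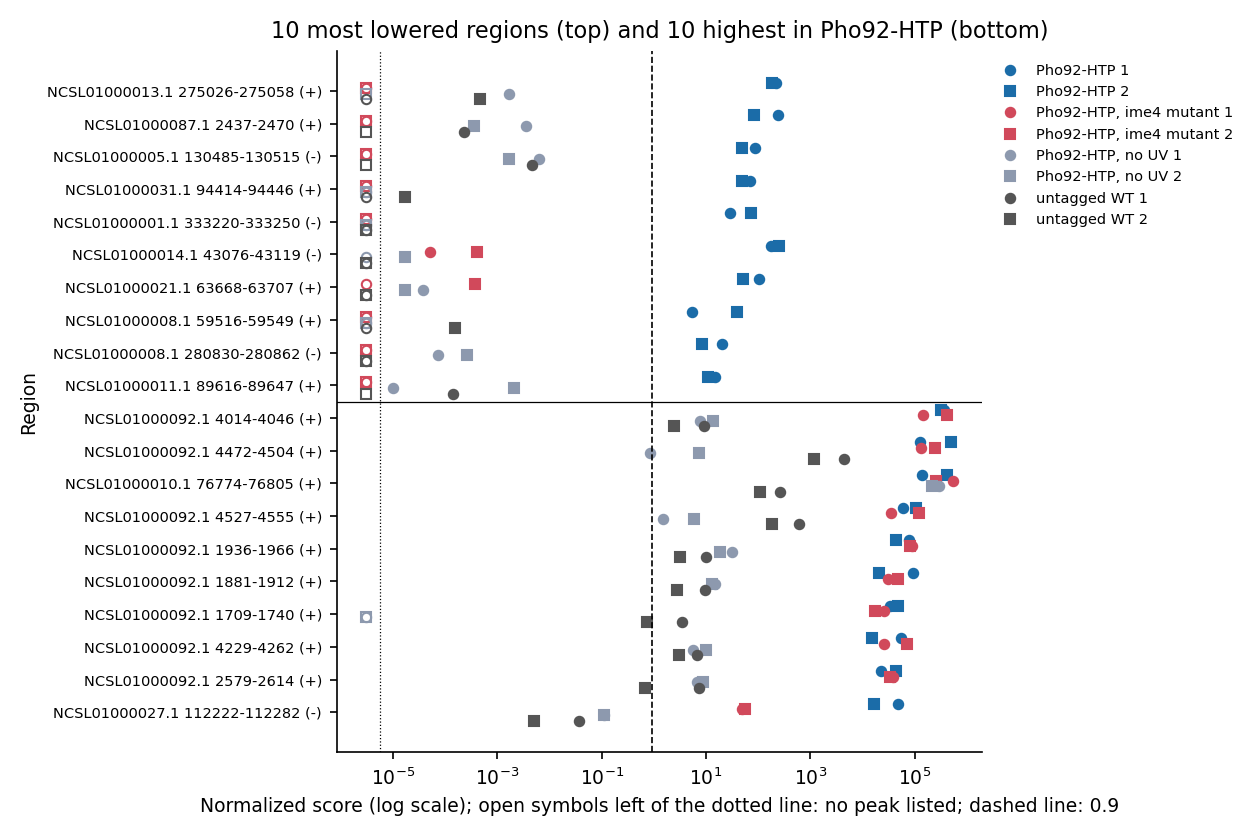
Normalized score per library on a log scale for the 10 most lowered regions (top) and the 10 regions highest in Pho92-HTP (bottom), with colours for groups, circles for replicate 1 and squares for replicate 2; open symbols left of the dotted line mark no listed peak, and the dashed line marks 0.9. In the 10 lowered regions both ime4 mutant libraries lie below 0.9, while in 9 of the 10 highest regions they lie at 17225 or more, and in the exception at 48.1 and 56.0.

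The libraries labelled untagged, scaled by the factors in their sheets, give the background of the purification. Nearly all strong Pho92-HTP sites stood above it: 914 of 964 tested regions were higher in Pho92-HTP and 0 were lower, also at an unadjusted p under 0.05 (limma on all 8 libraries). Regions were built from peaks of the irradiated Pho92-HTP libraries, so the untagged peaks above 0.9 outside them, 2 and 1 per library and all on contig NCSL01000092.1, could not count as lower. Of the 964 regions, 961 also passed the score filter on the 4 irradiated Pho92-HTP libraries alone. This selection favoured higher values in Pho92-HTP. Without the filter 17857 of 105079 regions were called higher and 2 lower (limma). For 448 of the 914 no peak was listed in either untagged library, and over the other 466 the median log2 score difference was 15.29. The 5 largest fitted differences included NCSL01000066.1 at 24130 to 24163, with 4973 and 4232 in Pho92-HTP against 0.00136 in untagged replicate 1 and no peak in replicate 2. NCSL01000055.1 at 18643 to 18723 (644 and 3443) and NCSL01000029.1 at 105149 to 105185 (488 and 779) each had a trace peak in 1 untagged library. The 2 others, on NCSL01000092.1 at 4784 to 4819 and at 3933 to 3961, had no listed untagged peak but untagged neighbours within 50 nt.

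Background was highest on contig NCSL01000092.1, which held 66.4% and 62.7% of summit read equivalents in the untagged libraries. At 4472 to 4504 it scored 4409 and 1183 in untagged cells against 128530 and 506313 in Pho92-HTP (log2 difference 6.80, SE 1.31, adjusted p = 0.00259, limma). At 4527 to 4555 the untagged scores were 606 and 186, at 3410 to 3440 they were 365 and 115, and at 1810 to 1839 they were 85.8 and 3.86. With scaling by library total or trimmed mean, the first 3 of these regions had a negative difference, from -2.22 to -0.13, of which that of -2.04 at 3410 to 3440 was called lower, and at 1810 to 1839 the call was lost. Those scalings gave 798 and 824 regions higher and 4 and 3 lower, and moved the median difference over all 964 regions from 16.36 to 12.68 and 11.54. NCSL01000010.1 at 76774 to 76805 scored 265 and 109 in untagged cells against 139280 and 423189 in Pho92-HTP.

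Omission of UV, in the libraries so labelled and scaled as in their sheets, gives the signal that does not need crosslinking. Here 888 of 964 regions were higher in Pho92-HTP with UV and 0 were lower, also at an unadjusted p under 0.05 (limma). Without UV 2 and 4 peaks above 0.9 lay outside the regions, all on contig NCSL01000092.1, and could not count as lower. The score filter favoured higher values in Pho92-HTP here too, and without it 17899 of 105079 regions were called higher and 1 lower (limma). For 402 of the 888 no peak was listed in either library without UV. The 5 largest fitted differences included NCSL01000092.1 at 1709 to 1740, with 33326 and 47350 in Pho92-HTP and no listed peak without UV, and NCSL01000008.1 at 1260 to 1291 (minus strand), with 9934 and 18841. The other 3, on NCSL01000092.1 at 1810 to 1839, 2409 to 2432 and 1348 to 1378, likewise had no listed peak without UV but did have peaks within 50 nt there, as did the first 2.

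A single peak made up most of the summed score without UV, but not most of the summit heights. NCSL01000010.1 at 76774 to 76805 (plus strand) held 90.6% and 79.7% of the score in those libraries, which squares the height, and 173585 of 421065 and 113093 of 334161 summit read equivalents. It scored 294379 and 217856 there against 139280 and 423189 in Pho92-HTP with UV (log2 difference -0.06, SE 0.74, adjusted p = 0.941, limma). The next 4 regions, NCSL01000002.1 at 149968 to 149998, NCSL01000001.1 at 445225 to 445256, and NCSL01000009.1 at 88258 to 88289 and at 347149 to 347180, had log2 differences from 0.05 to 0.73 and were not called. Under library-total scaling these 5 differences were -2.50 to -1.71, and under trimmed-mean scaling -8.58 to -7.79. By library total 3 of the 5 were called lower, and by trimmed mean all 5. With the factors of the normalization table the last 3 of the 5 turned negative, from -0.67 to -0.02, without a call. Over all 964 regions library-total scaling gave 873 higher and 15 lower, trimmed-mean scaling 742 higher and 32 lower, and the median difference went from 16.20 to 13.39 and 11.15.

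Both controls were exceeded by 884 regions, and these included all 577 that fell without IME4. Another 303 were above both controls and not called in either direction between genotypes, 252 of them with a log2 difference within 2. These comparisons share the Pho92-HTP libraries. In 100 simulations of unchanged groups no region was above both controls, and at most 1 was both lower in the mutant and above untagged. With no group changed hardly any region is called, so these simulations cannot show how much the shared libraries raise the overlap. Independent lists of these sizes would share 841.9 regions between the 2 controls, 548.8 between the lowered regions and those above untagged, and 533.2 between the lowered regions and those above no UV, and part of the excess may come from the shared libraries.

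Residual recovery without IME4 was asked by setting the ime4 mutant against untagged cells. Of 964 regions, 752 were higher in the mutant and 1 was lower (limma). Among the 577 regions that fell without IME4, 424 were still higher in the mutant than in untagged cells. The values were low: median scores of the 577 were 0.00680 and 0.00649 in the mutant, with summits of 13.1 and 17.8 read equivalents. In both untagged libraries the median score was 0. The 1 lower region, NCSL01000024.1 at 2458 to 2491 and named after its values were seen, scored 9.31 and 4.86 in Pho92-HTP, had no listed peak in the mutant, and scored 0.00159 and 0.000171 in untagged cells. The count of 752 depended on scaling: 457 regions were higher with library totals and 458 with a trimmed mean, and the median difference over all regions went from 9.66 to 4.59 and 4.89. The 424 were not recounted under these scalings and may be fewer there.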

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

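Leaving out contig NCSL01000092.1, regions from strong peaks only, regions listed in all 4 libraries, summit heights and the table's factors were alternatives chosen after the data were seen. Of the 584 regions called between genotypes, 579 were also called with scaling by library total (586 calls), 538 with a trimmed mean (558) and 550 with a block for the replicate number (562), although the numbers did not pair the libraries (correlation of deviations from -0.09 to 0.07). The remaining settings with all libraries and the same filter on scores gave 469 to 622 calls. Without the filter, calls were 3081 between genotypes, 17859 against untagged, 17900 against no UV and 11203 for the mutant against untagged, and with the stricter filter 343, 562, 539 and 474, as the number of regions tested sets them. Scaling by library total or trimmed mean moved the mutant's calls against untagged from 753 to 463 and 460. It raised the factors of the untagged libraries from 1.13 and 0.771 to 42.2 and 104, and to 9.61 and 14.1. These scalings take recovery to be alike in all libraries. Unscaled summed scores were 5248 and 2131 in untagged cells and 891454 and 1.64e+06 in the mutant. Leaving out 1 library gave 70 to 608 calls between genotypes, the lone sample assumed to vary like the other group, with 73 and 70 for a lone Pho92-HTP library, and 900 to 906, 877 to 882 and 714 to 794 in the control comparisons. With no spike-in scaling, ratios of summed score were 1.47 for Pho92-HTP over no UV (5.51 scaled) and 0.654 over the mutant (1.03 scaled), and that of peaks above the threshold was 2.51 (3.23 scaled). Without contig NCSL01000092.1 the ratios of summed score were 2624 over untagged (437 with it), 1.77 over no UV and 0.810 over the mutant (1.03 ± 0.292 with it, SD). Among the stronger 50% of all peaks, overlaps were 40.6% for Pho92-HTP, 50.4% for the mutant and 35.4% (other pairs 41.9%, 41.8% and 47.9%) between genotypes; this choice adds weak peaks. Of named values called at first, 458 stayed called in the same direction, 27 lost the call and 7 reversed; of those not called, 196 stayed so, 2 became called in the same direction and 35 reversed, 6 of these with a call. Reversed between genotypes on contig NCSL01000092.1 by trimmed mean were 4014 (0.55), 4472 (0.51), 4527 (0.70), 1881 (0.81) and 1709 (0.088), and by joining within 50 nt 1455 and 1936 (-0.039 each, in 1 joined region). Against untagged, 4472, 4527 and 3410 reversed by library total (-2.22, -1.12, -2.04) and trimmed mean (-1.22, -0.13, -1.04). Against no UV, NCSL01000002.1 149968, NCSL01000001.1 445225 and NCSL01000009.1 88258 and 347149 reversed by library total (-1.71, -1.74, -2.30, -2.39) and trimmed mean (-7.79, -7.82, -8.38, -8.47), and the last 3 with the table's factors (-0.024, -0.58, -0.67). With 1 library left out, uncalled differences between genotypes ranged from -1.19 to 0.31 (4014), -1.47 to 0.50 (4472), -0.17 to 1.43 (NCSL01000010.1 76774), -1.21 to 0.62 (4527), -1.28 to 0.92 (1881), -0.38 to 1.47 (4229) and -0.31 to 0.68 (2579). Those against no UV ranged from -0.86 to 0.74 (76774), -0.14 to 1.60 (149968), -0.14 to 1.54 (445225), -0.53 to 0.81 (88258) and -0.54 to 0.64 (347149). Reversals under another scaling come from the changed factors, and the cause of the other reversals was not tested. Alternatives planned for counts, RNA classes, gene lists, positions and motifs were not run, the unit being a score and no SK1 annotation being used here.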

Other observations

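The tests of the spike-in scaling, of the names of the control sheets and of the regions not above both controls were chosen only after the result was seen, and the others before. Fisher's test, the bootstraps and the Clopper-Pearson limit below count regions as independent, although regions share contigs and libraries. They measure spread over regions, not over libraries.

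Lower recovery in the ime4 mutant was weighed against 3 technical or indirect explanations. The 50 regions with control peaks above the threshold had a median log2 difference of 0.43, 7.95 above that of all other tested regions (bootstrap 7.28 to 8.54), and since 1 factor shifts all regions alike this argues against an error in the spike-in scaling as the whole cause. Joining regions within 50 nt left 574 called lower. Joins chain from peak to peak, so a joined region can be called lower through other peaks. This count therefore cannot decide on peaks listed at a shifted position. Differences of the 10 most lowered regions shrank with joining, and the median over all tested regions went from -6.95 to -5.26 (837 joined regions). A shift alone would leave the number of peaks above 0.9 alike. It was 1081 ± 28.3 in Pho92-HTP and 334.5 ± 2.12 in the ime4 mutant (SD, n = 2 each). That argues against shifted positions as the whole cause. Regions 50 to 500 nt from a lowered one had a median of -3.47 (990 regions, bootstrap -3.78 to -3.12). Those at 50 to 150 nt had one of -4.10 (363 regions, bootstrap -4.72 to -3.49). Summits of at least 10 read equivalents were required in both Pho92-HTP libraries but not in the mutant, which favours a fall. Of the 990, 153 were themselves called lower. Both medians lay above the bound of -5.11 set beforehand. That bound was a wrong one, because regions with no lowered one near, at -4.79, did not reach it either. Neighbours thus fell less, not more, than those regions. They were weak (median summits of 82.8 and 32.1 read equivalents in Pho92-HTP), and strength was not matched. Less of the bound transcripts in the mutant therefore stays open, as may an indirect effect of IME4 loss on the cells, which was not measured here.

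Regions not called lower in the mutant could be background. The test chosen beforehand went with this: 75.8% of the 384 had a peak in at least 2 of the 4 control libraries against 26.7% of the lowered regions (Fisher's exact p = 3.06e-52, two-sided), and outside contig NCSL01000092.1 73.4% (p = 2.91e-43). Looked at afterwards, 307 of the 384 stood above both controls, 270 of 334 outside that contig. Selection on scores above 0.9 in irradiated Pho92-HTP libraries favoured this, so it does not overrule the outcome written down first. Median scores of the 384 were 0.000602 and 0.000619 without UV and 0.000429 and 8.01e-05 in untagged cells. In Pho92-HTP they were 4.40 and 7.15. The same selection raised the Pho92-HTP medians, so these levels alone do not decide it. The peak lists were not selected in this way. Peaks above 0.9 numbered 334.5 ± 2.12 in the ime4 mutant, 54.5 ± 4.95 without UV and 26.5 ± 9.19 in untagged cells (SD, n = 2 each). For strong peaks that remain in the mutant, these numbers argue against background at the level of the controls as the whole account. Background as a part stays open. For the regions not above both controls, background at the level of the control libraries stays open: of the 29 above the threshold in both Pho92-HTP libraries, 0% were called lower by limma (95% Clopper-Pearson upper limit 11.9%), with differences from -0.22 to 1.52. Of these 29, 26 were above untagged and failed against no UV alone, so their signal may be independent of UV and not of the tag, while 5 lay on contig NCSL01000092.1. That reading rests on the names of the control sheets and would be reversed if they were exchanged. Nonspecific crosslinking to the tagged protein, and binding without m6A, were not measured by these controls and stay open.

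The control sheets carry the factor that the table lists for the other control. With the names of the control sheets exchanged, the table's peak numbers would go with the exchanged names, yet 7 of 8 entries equalled the number counted in the sheet of the same name. That bound, set after the result was seen, was a wrong one, because the peak numbers were made from the sheets themselves and carry their names. Exchanged names of sheets and exchanged factors cannot be told apart from these entries, and no biological explanation was tested.

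Of the 577 lowered regions, 155 had another within 500 nt on the same strand, against a median of 166 in 10000 shuffles of the calls (middle 95% 146 to 186). The bound set beforehand was a wrong one for several sites on one transcript, because the shuffles keep the spacing of the tested regions. They show that lowered regions did not lie closer together than tested regions do, and leave that explanation open. Outside contig NCSL01000092.1, regions were binned by their score in Pho92-HTP replicate 1, and the median difference of the mutant from Pho92-HTP replicate 2 was -2.04 at scores of 0.01 to 0.1 (7506 regions), -5.19 at 0.1 to 0.9 (2107), -7.92 at 0.9 to 10 (714), -8.60 at 10 to 100 (203) and -4.89 above 100 (91), where 52.7% were lower by more than 4-fold. Binned by ime4 mutant replicate 1, regions lower by more than 4-fold in Pho92-HTP than in ime4 mutant replicate 2 were 1030 of 4862 at 0.01 to 0.1, 125 of 814 at 0.1 to 0.9, 25 of 167 at 0.9 to 10, 4 of 55 at 10 to 100 and 0 of 68 above 100.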
